A study of Mus musculus with 18 samples.

How the data were processed

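ATAC-seq was carried out on 18 samples of mouse HSC and HPC in 6 groups, and the labels' protocols name tagmentation with Tn5 and no markers for the sort. Per the submitters' processing notes, Bowtie2 and MACS2 and the mouse build mm10, also called GRCm38, were used; their versions are not given in the sources used here. The labels give RNA as the extracted molecule, which is at odds with an assay of DNA, and this was not resolved. The deposited data used here were 6 peak lists, and all samples of a group name the same list in their labels. The lists were therefore taken to pool 2 samples for wild-type HSC, knockout HSC and knockout HPC and 4 for the other groups. How the reads of a group were combined before peak calling, and how the lists were filtered, is not given in the sources used here. Signal tracks, which the labels name once per group, were not analysed here, and no list of regions prone to mapping artifacts was used.

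Each row of a deposited list gives an interval and 4 values that the authors' peak caller produced. The deposited fold enrichment is the ratio of the signal at the summit to the local background of the same list. The deposited −log10 p of each row grows with sequencing depth, and its smallest value lay just above 2.00 in every list. The deposited score ran from 415 to 1000 and was not used further. The deposited summit is an offset in bp from the start of the interval. The lists held between 56976 rows in wild-type HSC and 163058 in vehicle HSC, and overlapping or repeated rows, which include separate summits of 1 interval, were merged into regions. That left 1.42 rows per region in wild-type HSC and 2.04 in vehicle HSC. The median region was 483 bp wide in wild-type HSC, 484 bp in knockout HSC, 481 bp in wild-type HPC, 462 bp in knockout HPC, 635 bp in vehicle HSC and 640 bp in 5-fluorouracil HSC. Read depth per sample was not known. A list grows with depth, with the number of samples pooled and with the threshold, so the number of regions found in a single list depends on all of these, and fold enrichment and −log10 p were ranked only within their own list. Ranks from lists of different lengths show no change at a region.

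A region was called present in another list where it overlapped a region there by at least 1 bp, and otherwise present in a single list. The comparisons were knockout against wild type in HSC and in HPC, 5-fluorouracil against vehicle in HSC, and HSC against HPC in wild type and in knockout. Across these, the HSC regions of a single genotype were looked up in the HPC lists, and regions that differed with 5-fluorouracil, or between vehicle HSC and wild-type HPC, were looked up in the 8-week HSC lists. These classes were defined without the lists they were looked up in. With a single list per group there was no model and no p-value. Shares carry 95% Wilson intervals, and the odds ratio a normal interval on the log scale. Regions were treated as independent for these, which neighbouring regions are not. Strength percentiles order the regions of a list by −log10 p. The strongest regions found only in 1 list were instead taken by fold enrichment, among those with no region of the other list within 1 kb.

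Coordinates are those of the files, on mm10, counted from 1. Genes came from a RefSeq gene table of GRCm38.p6, with 21883 protein-coding genes on the placed chromosomes. The table has no strand, so the planned rule, nearest start site within 100 kb, was replaced by the nearest gene body within 100 kb, with ties given to the nearer gene end. Both ends of a gene within 1 kb stood for its start. Between 93.2% of vehicle HSC regions and 94.7% of wild-type HSC regions had such a gene. Nearness does not show which gene a region acts on.

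The genes named in each comparison and direction followed a fixed rule. It took the 8 genes with the largest net number of regions in a single list, the genes nearest to the 5 regions of highest fold enrichment with no region of the other list within 1 kb, and from each gene list up to 4 members with the largest net number. Some of the genes it named are not reported here. The rule favours long genes. Net numbers leave out shared regions, so regions said to gather near a gene need not be a larger share there than over all regions. The median length of the genes it named by net number was 318.8 kb, against 17.2 kb for all protein-coding genes. Chromosome Y was left out of named regions. The comparisons, the rule, the gene lists and the other settings tried were chosen before the data were examined, except for the replaced gene rule and what is named as added below.

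There were 18 gene lists with 327 symbols, of which 4 were not among the protein-coding genes, and no gene was in more than 1 list. They covered stem cell identity and self-renewal, lymphoid progenitors, myeloid progenitors, erythroid and megakaryocyte genes, interferon and antigen presentation, interleukin-1, TNF and NF-kB signalling, cell cycle, chromatin regulators around Kmt2c, p53, DNA damage and apoptosis, fluoropyrimidine metabolism and efflux, fetal HSC, T and NK cells, mature B cells, neutrophils, macrophages, mast cells with basophils and eosinophils, stroma and endothelium, and housekeeping genes. For each list and comparison, the percentage of regions only in the first peak list minus that only in the second was placed among 10000 random gene lists of the same size, matched on the decile of the number of regions per gene. A list was said to stand apart below percentile 2.5 or above 97.5. This describes the lists and is not a test across samples.

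Settings tried besides these removed the weakest 25% of rows of each list, took an equal number of the strongest regions by −log10 p, asked for an overlap of at least 50% of the shorter region, called a region absent only with nothing within 1 kb, used 200 bp windows around summits, used autosomes only, or kept only regions above the median strength of their own list. For gene lists they also limited the nearest gene to 20 kb or used all 49939 annotated genes. Added after the data were seen were the nearest gene end in place of the gene body, the settings above applied to the named genes, and regions in both lists weighted to the strength of the regions in a single list in 50 bins. Leaving out replicates was not possible, and the planned motif search needed a genome sequence, which was not used here.

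The overlap and gene list steps were tested on simulated data made for knockout against wild-type HSC. All 2000 regions planted in the first list only and all 1000 planted in the second only were found among 30000 shared regions, and 1865 of the 2000 when nothing was allowed within 1 kb. Both lists were drawn from the vehicle list with edges moved by at most 30 bp, so full recovery was built in. It checks the overlap step only and not lists of unlike depth or threshold. Of 10 planted lists of 20 genes, with 40% of regions in the first list only against a background of 20%, 8 lay above percentile 97.5. Of 200 lists without an effect, 9, or 4.5%, lay outside the bounds. That step ran on 15488 genes. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.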

Results

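Open chromatin was profiled by ATAC-seq, which marks accessible DNA with the Tn5 transposase, in mouse haematopoietic stem cells (HSC) and in cells labelled HPC, the more mature progenitors. The 18 samples fell into 6 groups. At 8 weeks of age there were 2 wild-type HSC samples, 2 HSC samples with Kmt2c deleted in blood cells by Vav-Cre, 4 wild-type HPC samples and 2 Kmt2c knockout HPC samples. At 16 weeks there were 4 wild-type HSC samples given vehicle and 4 given 5-fluorouracil, a drug that kills dividing cells, at 150 mg/kg, both in 3 injections spaced 3 weeks apart. The title of the series names activated and quiescent HSC, Kmt2c mutation and chemotherapy, so the comparisons ask how the accessible regions of HSC differed with the loss of Kmt2c, with repeated 5-fluorouracil and between HSC and progenitors.

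The wild-type HSC list held 40073 accessible regions, the knockout HSC list 48620, the wild-type HPC list 65832, the knockout HPC list 52840, the vehicle HSC list 80100 and the 5-fluorouracil HSC list 71363. Together these covered between 21.2 Mb in wild-type HSC and 55.9 Mb in vehicle HSC. An accessible region lay at an annotated end of 11310 of 21883 protein-coding genes in wild-type HSC, 12069 in knockout HSC, 13066 in wild-type HPC, 11932 in knockout HPC, 14297 in vehicle HSC and 13842 in 5-fluorouracil HSC. Regions at a gene end made up 28.2% of the wild-type HSC list (95% Wilson interval 27.7 to 28.6), the shortest, and 19.6% (19.3 to 19.9) of the vehicle list, the longest. Read depth was not given in the files. The files used here hold a single list per group, so replicates were not compared and no test across samples was made. The intervals below cover counting error over regions only.

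Kmt2c, the deleted gene, encodes a histone H3 lysine 4 methyltransferase that acts at enhancers. It spans 25271795 to 25498855 on chromosome 5 of mm10, and its upper end carried an accessible region in all 6 lists. In wild-type HSC that region ran from 25498802 to 25500056 with a fold enrichment over local background of 8.04, and in knockout HSC from 25498678 to 25500345 with 6.98. The fold enrichment was 8.55 in wild-type HPC, 10.8 in knockout HPC, 7.42 in vehicle HSC and 8.10 in 5-fluorouracil HSC. A region inside the gene, starting near 25436126, was in every list except that of wild-type HSC. Another, starting near 25472065, was in the knockout HSC, vehicle and 5-fluorouracil lists. A further one, starting near 25420626, was in the wild-type HPC, vehicle and 5-fluorouracil lists. It was in neither knockout list, but also not in that of wild-type HSC. The deleted part of the gene is not given in the labels, so these regions neither check nor question the genotype.

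**Figure D1:**
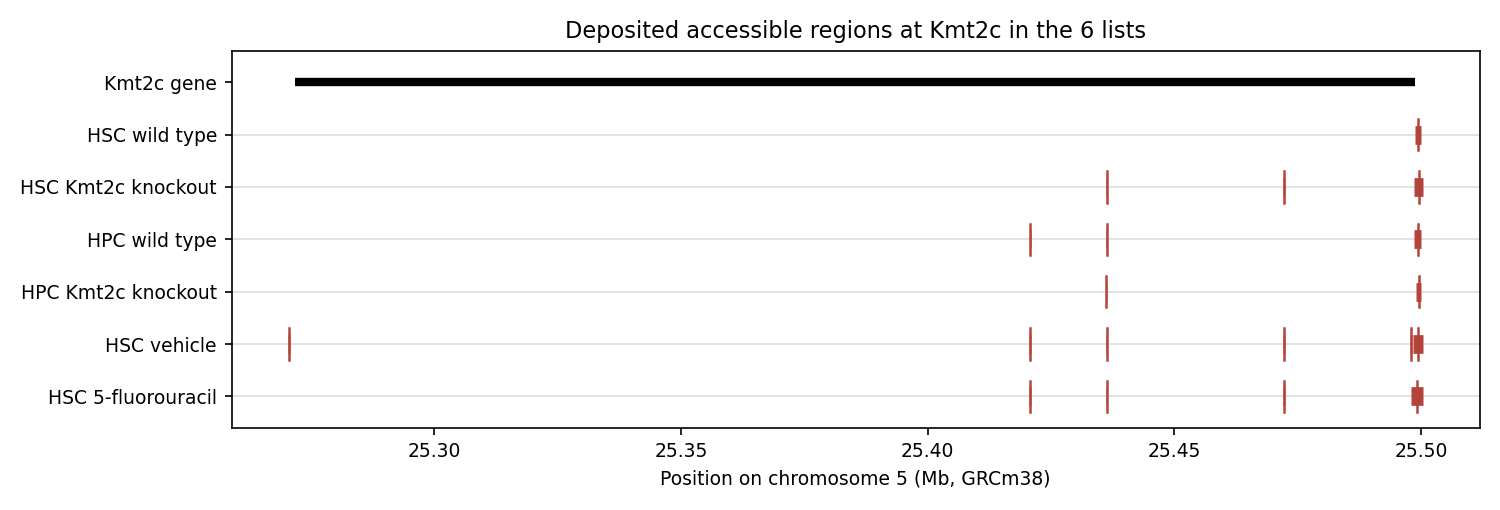
Accessible regions along Kmt2c in the 6 peak lists, by position on chromosome 5 (Mb, mm10), with a row of bars per group and the gene body from 25271795 to 25498855. All 6 lists hold a region at the upper end of the gene, and wild-type HSC alone lack the region inside the gene near 25436126.

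The first comparison asked where chromatin was open in HSC without Kmt2c and not in wild-type HSC, or the reverse. Regions present only in knockout HSC gathered near Prkce, which encodes protein kinase C epsilon, with 11 knockout-only regions and 0 wild-type-only ones. Hivep3, a zinc finger transcription factor, had 12 and 2. Nav2, a neuron navigator, had 11 and 1, and Grik4, a kainate receptor subunit, 10 and 0. Nfatc2, a calcium-regulated transcription factor of lymphocyte activation, had 9 and 0, as had Btbd9 and Spata13, and Arhgap26 had 12 and 4. Prkce, Hivep3, Nfatc2 and Arhgap26 were also named for wild-type HPC over the same wild-type HSC list. There they had 23 HPC-only regions against 3, 22 against 2, 22 against 1 and 20 against 2. Nav2, Grik4, Btbd9 and Spata13 were not named there. Of all knockout-only regions 93.3% were in the vehicle list, also of wild-type HSC. The counts per gene therefore cannot tell sites opened without Kmt2c from a short wild-type HSC list. Regions present only in wild-type HSC gathered near Filip1l and Mb21d2, with 4 and 0 each, and near Pde4d, a cyclic AMP phosphodiesterase, with 6 wild-type-only and 3 knockout-only regions. Stox2 and Cradd, the latter an adaptor of cell death signalling, had 4 and 1, and B3gnt5, a glycosyltransferase, Kif5c, a kinesin heavy chain, and Otogl had 3 and 0.

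By fold enrichment, and with no wild-type region within 1 kb, the strongest region found only in knockout HSC lay outside Gabrr1, a GABA receptor subunit gene. It ran from 33124471 to 33124861 on chromosome 4, with a fold enrichment of 30.3 that ranked 2043 of 48620. Others were near the ubiquitin ligase gene Rnf144b, with a fold enrichment of 29.4, and inside Dennd5a, a regulator of Rab GTPases, with 28.8. The strongest found only in wild-type HSC lay within Slc8a1, a sodium and calcium exchanger, at 81480319 to 81480865 on chromosome 17, with a fold enrichment of 34.8 that ranked 269 of 40073. The next lay within Stim1, a calcium sensor of the endoplasmic reticulum, at 102337881 to 102338386 on chromosome 7, with 29.6 and rank 1437. Regions near Sptssb, a subunit of the enzyme that starts sphingolipid synthesis, and near Arid3b followed with 24.4 and 24.0. The remaining regions among the 5 strongest of each direction had no protein-coding gene within 100 kb.

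In all, 12589 of 48620 knockout HSC regions, 25.9% (25.5 to 26.3), were absent from wild-type HSC, and 4004 of 40073 wild-type regions, 9.99% (9.70 to 10.3), were absent from knockout HSC. The list-specific regions were weak. Knockout-only regions had a median strength percentile of 17.1 in their own list, against 62.7 for shared regions, and 14.3% of them lay at a gene end, against 29.5% of shared ones. With each list limited to its 40073 strongest regions, 6148 were only in knockout and 6042 only in wild-type HSC. Lists of equal length make such counts nearly equal by construction, in this and the other comparisons, and take any general excess out of the counts per gene. Their balance therefore does not show why one count was larger as deposited. Only the longer list of a pair is shortened, so the excess of a gene named for the shorter list cannot become smaller. At that equal number Prkce had 7 knockout-only regions against 1, Hivep3 4 against 2, Nav2 6 against 5, Grik4 6 against 2, Btbd9 6 against 1, Nfatc2 6 against 0, Arhgap26 8 against 4 and Spata13 3 against 3. With regions given to the nearest gene end in place of the gene body, Prkce had 4 and 0, Nav2 1 and 1, Hivep3 and Grik4 6 and 0 each, Btbd9 and Arhgap26 3 and 0 each, and Pde4d 1 wild-type-only region against 0. With the weakest 25% of each list removed Hivep3 had 7 and 2, and Cradd 1 wild-type-only region against 1.

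**Figure D2:**
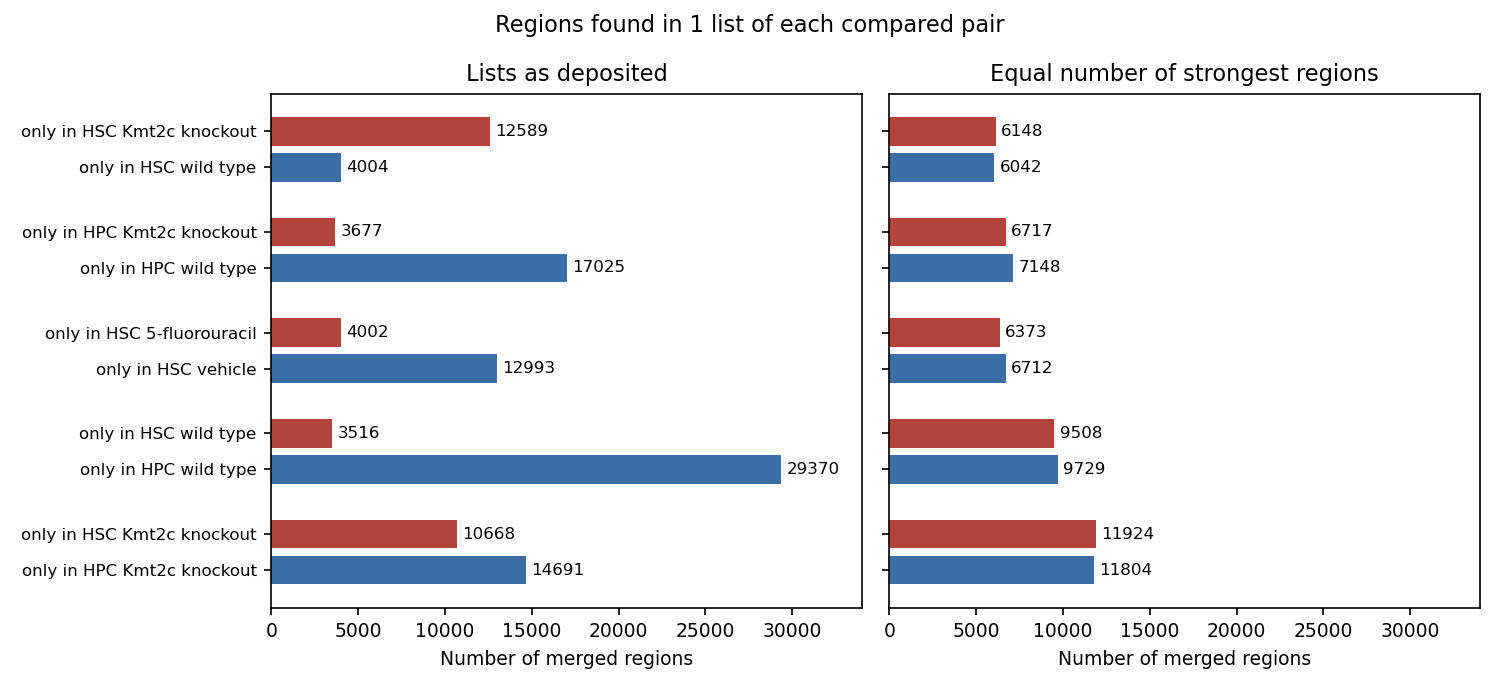
Number of regions present in a single list of each comparison, as deposited and with both lists limited to an equal number of their strongest regions. In HSC the knockout-only count is 12589 against 4004 as deposited and 6148 against 6042 at equal number, where the balance follows from the equal lengths.

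Among 41 genes of stem cell identity and self-renewal, 25 had more knockout-only and 3 more wild-type-only regions in HSC. Mecom, a transcription factor that maintains HSC, had 8 knockout-only, 3 wild-type-only and 13 shared regions, Kit, the receptor of stem cell factor, 5, 0 and 6, Runx1 5, 0 and 16, and Prdm16 9, 5 and 11. Of 32 genes of interleukin-1, TNF and NF-kB signalling, 18 had more knockout-only and 3 more wild-type-only regions. Nfkb1 had 6 and 1 and the interleukin-1 receptor gene Il1r1 4 and 1. Of 25 genes of the p53 and apoptosis list the counts were 12 and 1, with 7 and 2 regions near the survival gene Bcl2. Among lymphoid progenitor genes they were 14 and 1, with 5 and 1 near Bcl11a and 3 and 0 near Lef1, and among myeloid progenitor genes 9 and 3, with 5 and 1 near Cebpb and 4 and 0 near Itgam. At equal number the genes with more knockout-only and with more wild-type-only regions were 10 and 10 for self-renewal, 6 and 9 for interleukin-1, TNF and NF-kB, 6 and 6 for p53 and apoptosis, 5 and 6 for lymphoid and 4 and 6 for myeloid genes.

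Set against random gene lists with as many regions, a single list of the 18 stood apart between knockout and wild-type HSC. Macrophage marker genes had 9 knockout-only regions and 1 wild-type-only region, at percentile 99.4, with 5 and 0 near the scavenger receptor gene Marco and 2 and 1 near Mertk, and at equal number the percentile was 97.0 with 4 regions against 1. The other lists lay within the central 95% of random lists. Self-renewal genes were at 74.6, lymphoid progenitor genes at 70.8, myeloid progenitor genes at 47.5 and erythroid and megakaryocyte genes at 25.5. Interferon and antigen presentation genes were at 21.8, interleukin-1, TNF and NF-kB genes at 45.7, cell cycle genes at 10.7 and p53 and apoptosis genes at 78.6. Chromatin regulators, which include Kmt2c and its complex, were at 32.8, fluoropyrimidine and efflux genes at 60.1 and fetal HSC genes at 12.5. Markers of T and NK cells were at 53.9, of mature B cells at 26.0, of neutrophils at 86.7, of mast cells, basophils and eosinophils at 76.8 and of stroma and endothelium at 28.7. Housekeeping genes were at 37.3. Over all 5 comparisons, 10 of 90 list percentiles lay outside the central 95%, where chance gives 4.5.

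**Figure D3:**
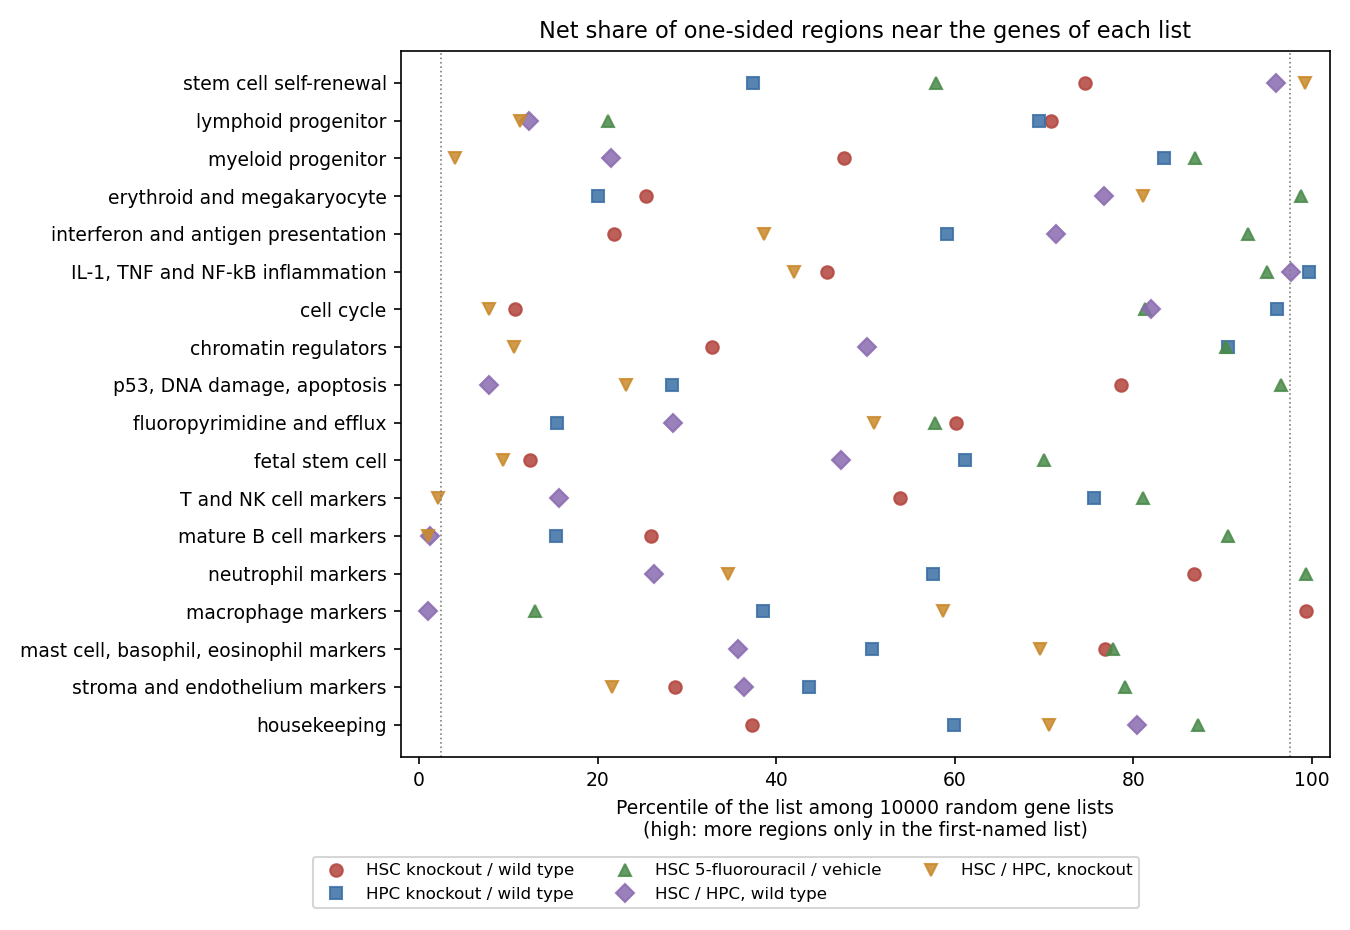
Percentile of each of the 18 gene lists among 10000 random lists matched on their number of regions, for the 5 comparisons, with bounds that hold the central 95% of random lists. In HSC knockout against wild type the macrophage list alone lies outside, at 99.4.

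In progenitors the same genotypes were compared, 2 knockout samples against 4 wild-type ones, and the regions found in a single list were mostly those of wild-type HPC. Pde4d had 20 regions present only in wild-type HPC and 1 only in knockout HPC, and Wwox, an oxidoreductase gene deleted in some cancers, 19 and 2. Bcor, a corepressor of BCL6, had 14 and 1, Med13l, a Mediator subunit, 14 and 2, and Maml3, a Notch coactivator, 14 and 2. Gabbr2, a GABA receptor subunit, had 12 and 0, Nfia, a transcription factor, 15 and 4, and Tenm4 14 and 3. Fewer regions were found only in knockout HPC. Foxo6, a forkhead factor, had 4 and 0, Cacnb4, a calcium channel subunit, 4 and 1, and Inpp4b, a phosphoinositide phosphatase, Rab20, Focad, Asic4 and Triobp 3 and 0. These counts depended on weak regions. With the weakest 25% of each list removed Foxo6 had 2 and 0, Cacnb4 1 and 1, Inpp4b 1 and 0, Rab20 and Focad 2 and 1 each and Asic4 0 and 0, and with nothing allowed within 1 kb Foxo6 had 1 and 0. Inpp4b and Focad had 0 and 0 with the nearest gene end.

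The strongest regions found only in wild-type HPC lay within Arhgap35, at 16558176 to 16558524 on chromosome 7, with a fold enrichment of 41.3 that ranked 25 of 65832, and at an end of Dync1i2, a dynein subunit, at 71211514 to 71212074 on chromosome 2, with 40.1 and rank 55. Gm3636 and the polarity gene Pard3 followed with 37.9 and 29.2. Those found only in knockout HPC with a gene within 100 kb lay in or near Tbc1d19, with 27.5, Atf6, a transcription factor of the endoplasmic reticulum stress response, with 27.2, Tex29, with 26.3, and Adgrf1, with 24.0. As deposited, 17025 of 65832 wild-type HPC regions, 25.9% (25.5 to 26.2), were absent from knockout HPC and 3677 of 52840 knockout regions, 6.96% (6.74 to 7.18), from wild-type HPC. At an equal number of 52840 regions the counts were 7148 and 6717. Wild-type-only regions near Pde4d were then 8 against 4, near Wwox 8 against 3, near Bcor 7 against 4, near Med13l 9 against 2, near Gabbr2 3 against 0, near Maml3 3 against 3, near Nfia 5 against 4 and near Tenm4 6 against 3. With the nearest gene end Pde4d had 5 and 0, Wwox 10 and 1, Maml3 8 and 1, Gabbr2 7 and 0 and Tenm4 4 and 2, and with the weakest 25% removed Gabbr2 had 7 and 0.

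By group, 29 of 41 self-renewal genes had more wild-type-only HPC regions and 3 more knockout-only ones. Prdm16 had 6 wild-type-only and 0 knockout-only regions, Lmo2 and Thy1 5 and 0 each, and Runx1 7 and 3. Of 25 lymphoid genes 18 had more wild-type-only regions and 1 more knockout-only ones, with 5 and 0 near Satb1, and of 25 p53 and apoptosis genes 15 and 1. At equal number these counts were 12 and 11 for self-renewal, 7 and 6 for lymphoid and 7 and 5 for p53 and apoptosis genes. Of 20 chromatin regulators 8 had more wild-type-only and 5 more knockout-only regions, at percentile 90.6, and at equal number 3 and 8. Ep300, a histone acetyltransferase, and Smarca4, a remodelling ATPase, had 4 wild-type-only regions against 0, Arid1a, a subunit of a remodelling complex, 3 against 0, and Dnmt3a, a DNA methyltransferase, 2 only in knockout HPC and 0 only in wild type. The interleukin-1, TNF and NF-kB list stood apart, at percentile 99.7, with 15 knockout-only and 34 wild-type-only regions, a smaller wild-type excess than random lists had. Jun had 0 and 6 of these and Fos 3 and 1. At equal number that percentile was 44.7, on the other side of the middle, and with the weakest 25% removed it was 78.9.

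The knockout difference in HSC was set beside that in HPC by asking in which HPC list the HSC regions of a single genotype were found. Of wild-type-only HSC regions in exactly 1 HPC list, 86.3% (84.2 to 88.2) of 1127 were in wild-type HPC, against 81.5% (80.1 to 82.8) of 3077 knockout-only HSC regions. The wild-type list held 82.2% of all regions of exactly 1 HPC list. The odds ratio for the same genotype in both cell types was 1.44 (1.18 to 1.74), with an interval over regions only. With windows of 200 bp around summits it was 1.03 (0.912 to 1.16), which includes 1.

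In both knockout lists and in no wild-type list were 27 regions. They lay near Ncs1, a neuronal calcium sensor, Map2k5, a kinase of the ERK5 pathway, Rxra, a retinoid receptor, Stat3, a cytokine signalling factor, Etv6, a transcription factor needed by adult HSC, and Bak1, a trigger of apoptosis, among others. The region near Ncs1 ran from 31268611 to 31268997 on chromosome 2 with a fold enrichment of 12.0 in knockout HSC. The highest of the 27, near Septin5, was 12.7. The regions near Rxra, Etv6, Bak1 and Stat3 had 7.27, 6.02, 4.06 and 3.50. The 27 were weak regions, with a median strength percentile of 6.71. In the reverse direction 873 regions were in all 4 wild-type lists and in neither knockout list. Their median strength percentile was 11.9 in wild-type HSC and 18.6% of them lay at a gene end. The 27 had to be absent from all 4 wild-type lists, among them those of vehicle and 5-fluorouracil HSC, with 80100 and 71363 regions. The 873 had to be absent only from the knockout lists, of 48620 and 52840 regions. The numbers 27 and 873 are therefore not comparable and do not show more regions lost than gained without Kmt2c.

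The next comparison asked what differed in HSC that had been through 3 rounds of 5-fluorouracil. Regions present only after 5-fluorouracil gathered near Sox5, a transcription factor, with 9 regions against 2 only in vehicle HSC, and near Itpr2, a calcium release channel, with 5 and 0. Ezh2, the methyltransferase of Polycomb complex PRC2, had 4 and 0, Itpk1, an inositol phosphate kinase, 4 and 0, Fam107b 5 and 1, Robo1 6 and 2, Chn2 5 and 2 and Sgms1, a sphingomyelin synthase, 9 and 6. Regions present only in vehicle HSC gathered near Nrxn3, a neurexin, with 12 and 0, Erc2 with 11 and 0 and Mbnl1, a splicing regulator, with 13 and 3. Gse1 had 12 and 2, Auts2 10 and 0, the transcription factor gene Sox6 10 and 1, Prkce 10 and 1 and Myo16 9 and 0. Shared regions are left out of these counts, so they do not show a share above that of all vehicle regions. With the nearest gene end Nrxn3 had 1 and 0, Erc2 and Sox6 3 and 0 each, Gse1 4 and 1, Auts2 2 and 0, Prkce and Myo16 4 and 0 each, and on the 5-fluorouracil side Sox5 3 and 1 and Robo1 2 and 1.

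By fold enrichment, and with no vehicle region within 1 kb, the strongest region found only after 5-fluorouracil lay within Arpp21. It ran from 112186188 to 112187051 on chromosome 9, with a fold enrichment of 24.9 that ranked 3692 of 71363. Regions within Lgmn, a lysosomal protease, and Gldc, the glycine decarboxylase, had 22.2 and 21.9, and those near Col19a1 and within Kctd1 18.9 and 18.6. Whether the region near Col19a1, at 24612996 to 24613234 on chromosome 1, came from reads of mitochondrial DNA was not tested. The strongest found only in vehicle HSC near a gene lay within Kat6b, a histone acetyltransferase, at 21653696 to 21654472 on chromosome 14, with 25.2 and rank 3802 of 80100, followed by regions in or near Pappa2, with 22.6, Ptpra, with 21.4, and Rai14, with 21.2. In all, 4002 of 71363 regions, 5.61% (5.44 to 5.78), were only in the 5-fluorouracil list and 12993 of 80100, 16.2% (16.0 to 16.5), only in the vehicle list. At an equal number of 71363 the counts were 6373 and 6712. At that number Mbnl1 had 6 vehicle-only regions against 3, Sox6 and Prkce 4 against 1 each, Auts2 8 against 2, and Gse1 5 against 6. With the weakest 25% removed Sgms1 had 5 only after 5-fluorouracil and 6 only in vehicle HSC, Chn2 2 and 2 and Itpk1 2 and 0, and Prkce 6 vehicle-only regions against 1.

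Self-renewal genes did not stand apart with 5-fluorouracil, at percentile 57.9, though, like all regions, theirs were more often only in vehicle HSC. Mecom had 11 vehicle-only, 4 5-fluorouracil-only and 37 shared regions, Mllt3 10, 4 and 20, and Hlf, a transcription factor of quiescent HSC, 6, 0 and 15. Of the 41 self-renewal genes 19 had more vehicle-only and 7 more 5-fluorouracil-only regions, and at equal number 10 and 13. Ebf1, a B lymphoid factor, had 8 vehicle-only regions and 0 only after 5-fluorouracil, and Atf3, a stress-induced factor, 4 and 0. Erythroid and megakaryocyte genes stood apart at percentile 98.8, with 7 regions only after 5-fluorouracil and 8 only in vehicle HSC, where random lists had a larger vehicle excess. Gata1, the erythroid transcription factor gene, and Hbb-bt, a beta globin gene, had 1 region each only after 5-fluorouracil and 0 only in vehicle HSC, Add2, a membrane skeleton gene, 2 and 1, and Ank1, another, 0 and 1. With the nearest gene end the percentile of this list was 97.2, inside the central 95%. Neutrophil markers were at 99.3 on 2 regions near Mmp8, a neutrophil collagenase, against 0, at 40.7 once the weakest 25% of each list was removed and at 78.6 with all annotated genes.

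HSC and progenitors were also compared within each genotype. In wild type, HSC-only regions gathered near Vac14, a phosphoinositide kinase scaffold, with 5 and 0, near the adhesion genes Ncam2 and Lsamp with 5 and 2 each, near Itga6, an integrin chain, with 4 and 2, and near Adam12, Camsap3, Ptpn4 and Lnx1 with 3 and 0. Ncam2 had 2 and 2 and Lsamp 1 and 2 with the nearest gene end. The strongest lay within Exoc6b, an exocyst subunit, at 84883007 to 84883594 on chromosome 6, with a fold enrichment of 32.3 that ranked 680 of 40073, and others were within Opcml, with 30.5, at an end of the imprinted gene Zim1, with 28.7, and near Hao2, with 28.5. HPC-only regions gathered near Pde4d with 26 and 3, Wwox with 24 and 0, Gse1 with 24 and 1, Maml3 with 23 and 0, Prkce with 23 and 3, Nfatc2 with 22 and 1, Hivep3 with 22 and 2 and Arhgap26 with 20 and 2. The strongest lay within Rab39, a small GTPase, with 41.8 and rank 20 of 65832, within Trim36, a ubiquitin ligase, with 41.0, within Dnah7a, a dynein heavy chain, with 39.4, and near Cdc14a, a phosphatase, and Zfp874b, with 39.3 and 39.0.

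Of 65832 wild-type HPC regions, 29370 or 44.6% (44.2 to 45.0) were absent from wild-type HSC, and 3516 of 40073 HSC regions, 8.77% (8.50 to 9.06), were absent from HPC. At an equal number of 40073 regions the counts were 9729 and 9508. In the lists as deposited Runx1 had 16 HPC-only regions against 0, Erg 11 against 2, the cell cycle kinase gene Cdk6 11 against 0 and Itgam 9 against 0. Marco and Satb1, a chromatin organiser of lymphoid cells, had 8 against 0 each. Of the 18 gene lists 3 stood apart, and the self-renewal, cell cycle, myeloid and lymphoid lists were not among them. Macrophage markers, at percentile 0.985, and mature B cell markers, at 1.27, had the larger HPC excess, with 15 HPC-only regions against 1 and 8 against 0, though mature B cell markers were at 3.45 with all annotated genes. Interleukin-1, TNF and NF-kB genes were at 97.6, with 75 HPC-only and 15 HSC-only regions, and at 81.3 at equal number. At equal number the HPC-only regions near Pde4d were 8 against 10, near Wwox 4 against 2, near Gse1 6 against 5, near Maml3 8 against 1, near Nfatc2 9 against 1, near Prkce and Hivep3 7 against 5 each and near Arhgap26 7 against 4. Counted by the nearest gene end they were 6 against 0 near Pde4d, 11 against 0 near Wwox, 7 against 1 near Gse1, 12 against 0 near Maml3, 10 against 2 near Prkce, 8 against 1 near Hivep3 and 4 against 1 near Arhgap26.

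In knockout cells, HSC-only regions gathered near Aff3, a nuclear factor first found in lymphoid cells, with 11 and 1, Nav2 with 12 and 6, Thsd4 with 9 and 1, Prdm16 and Slc8a1 with 8 and 2 each and D7Ertd443e and Fry with 8 and 1 each. HPC-only regions gathered near Gse1 with 17 and 6, Fyn, a Src family kinase, with 14 and 2, Pard3 with 12 and 2, Sdk1 with 11 and 1, Zfp704 with 11 and 2, Rptor, a subunit of the growth regulator mTORC1, with 10 and 1, and Abtb2 and Fstl4 with 10 and 1 each. With the nearest gene end Nav2 had 1 HSC-only region against 4, Aff3 4 against 0 and Thsd4 5 against 1, and the HPC-only regions were 3 against 0 near Gse1, 5 against 1 near Pard3, 2 against 0 near Sdk1 and 3 against 1 near Fstl4. With the weakest 25% removed those near Gse1 were 11 against 8. The strongest HSC-only regions lay at Dync1i2 with a fold enrichment of 40.0, within Arhgap35 with 39.0 and within Opcml with 37.0. The strongest HPC-only ones lay within Usp32, a deubiquitinase, with 37.1, Dnah7a with 37.0, Trim36 with 36.0 and Slc8a1 with 35.8. The regions at Dync1i2 and within Arhgap35 were also in wild-type HPC, with 40.1 and 41.3, and were missing only from the knockout HPC list. That within Slc8a1 was also in wild-type HSC, with 34.8, and was missing only from the knockout HSC list. These regions therefore do not separate HSC from HPC in wild type. In all, 14691 of 52840 knockout HPC regions, 27.8% (27.4 to 28.2), were absent from knockout HSC and 10668 of 48620 HSC regions, 21.9% (21.6 to 22.3), from knockout HPC. Self-renewal genes stood apart at percentile 99.2, with 83 HSC-only regions against 77, among them Prdm16 with 8 and 2, though Runx1 had 2 and 9 and Erg 4 and 10. Between wild-type HSC and HPC the self-renewal list did not stand apart. That comparison rests on the short wild-type HSC list, and the difference between the genotypes was not tested. T and NK cell markers, at 2.11, and mature B cell markers, at 1.05, had the larger HPC excess, with 13 HPC-only regions against 4 and 5 against 1. None of these 3 lists stood apart under every setting. Self-renewal genes were at 96.7 with the nearest gene end, and with all annotated genes T and NK cell markers were at 4.76 and mature B cell markers at 12.9.

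Regions that separated 16-week vehicle HSC from wild-type HPC served to ask whether the knockout HSC list held more stem cell or more progenitor regions than the wild-type one. The groups that define them also differed in age, in the injections and in list length, so stem cell and progenitor regions are short names only. Knockout HSC held 22.0% (21.5 to 22.5) of 26356 regions of vehicle HSC absent from HPC and wild-type HSC 12.0% (11.6 to 12.4). Of 10034 regions of HPC absent from vehicle HSC, knockout HSC held 5.42% (5.00 to 5.88) and wild-type HSC 1.86% (1.62 to 2.15). Of regions in both they held 75.1% and 65.9%. Of regions in exactly 1 of these 8-week HSC lists, the knockout share was 79.1% (77.9 to 80.3) for stem cell regions, 83.5% (80.1 to 86.4) for progenitor regions and 74.4% (73.5 to 75.2) for regions in both. With every list limited to its 40073 strongest regions and the classes drawn anew, these shares were 52.2% (50.5 to 54.0), 54.0% (51.8 to 56.2) and 59.4% (57.5 to 61.3), with the highest for regions in both.

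Regions that differed with 5-fluorouracil were followed in the same way. Knockout HSC held 6.77% (6.03 to 7.59) of 4002 regions found only after 5-fluorouracil and wild-type HSC 2.37% (1.95 to 2.89). Of 12993 vehicle-only regions they held 11.8% (11.2 to 12.3) and 4.63% (4.29 to 5.01), and of regions in both 66.3% and 56.4%. Among regions in exactly 1 of the 8-week HSC lists, the knockout share was 82.1% (77.1 to 86.2) of 274 for regions only after 5-fluorouracil, 81.6% (79.6 to 83.5) of 1469 for vehicle-only regions and 75.2% (74.5 to 76.0) of 13173 for regions in both. With every list limited to its 40073 strongest regions the classes held other regions, 2648 of them only after 5-fluorouracil and 805 of these in exactly 1 of the 8-week HSC lists. The shares in those classes were 43.9% (40.5 to 47.3), 57.7% (54.4 to 60.9) and 55.0% (53.6 to 56.4).

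**Figure D4:**
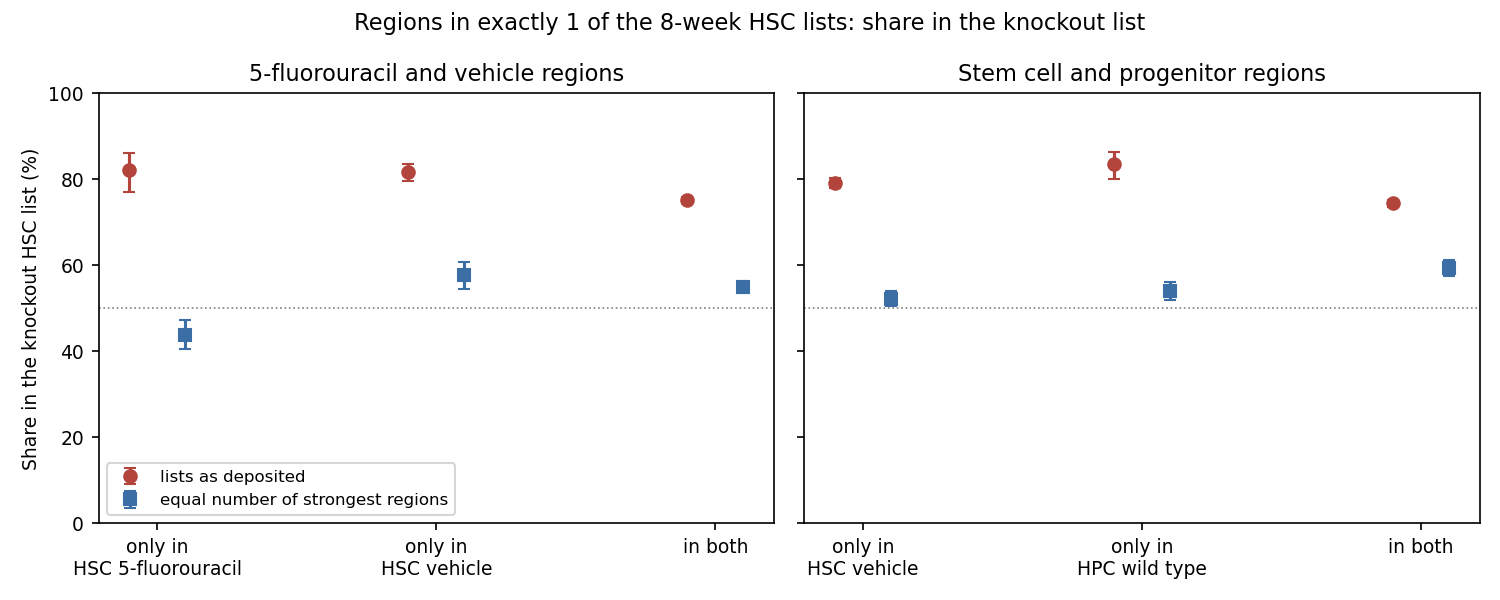
Share, in percent with 95% Wilson intervals, of regions in exactly 1 of the 8-week HSC lists that are in the knockout list, for regions that differ with 5-fluorouracil and between HSC and HPC, as deposited and with the classes drawn anew from the 40073 strongest regions of every list. Regions only after 5-fluorouracil are at 82.1% of 274 as deposited, and a different set of 805 is at 43.9% at equal number.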

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

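The predictions tested in this part were written before their results were seen. No prediction was chosen afterwards, but the search for stronger regions missing from a single list was. The ratio of knockout-only to wild-type-only regions was 3.14 in HSC and 0.216 in HPC, on opposite sides of 1. This difference between the cell types was not tested, since each group had a single list.

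The larger number of regions found only in knockout HSC was weighed against list length and against progenitor cells in the sort. Of the knockout-only regions 93.3% (92.8 to 93.7) were in the longer list of vehicle-treated wild-type HSC. This was slightly below the 96.0% (95.4 to 96.6) of wild-type-only regions, beyond the intervals. A knockout list that reached weaker regions open in wild-type HSC too would give such shares. A region that only gained strength without Kmt2c could be in the long vehicle list as well, so the shares cannot set such a gain apart. Of those absent from the vehicle list, 52.7% (49.3 to 56.0) of 849 knockout-only and 56.3% (48.5 to 63.7) of 160 wild-type-only regions were in wild-type HPC, so progenitors in the knockout sort and none cannot be told apart at these counts. Myeloid progenitor genes were at percentile 47.5 and lymphoid ones at 70.8 between knockout and wild-type HSC. However, 20 of 25 and 18 of 25 of these genes had a region in wild-type HSC as well. Macrophage markers were at percentile 99.4, on 9 knockout-only regions against 1, and at 97.0 at equal number. Between wild-type HSC and HPC they were at 0.985, towards HPC. Both percentiles rest on the same wild-type HSC list, so the second is not separate support. Macrophage genes had 6 regions in wild-type HSC, 14 in knockout HSC, 21 in wild-type HPC and also 21 in vehicle-treated wild-type HSC. These counts therefore cannot tell more mature cells from a short wild-type HSC list. Mature B cell and T and NK cell markers were at 26.0 and 53.9 between knockout and wild-type HSC. No gene was in more than 1 list, and the labels name the sorted cells without the markers of the gate. Most regions of either kind were weak. Above the median strength of their own list lay 675, or 5.36%, of 12589 knockout-only HSC regions. Of 4004 wild-type-only regions 64, or 1.60%, did. Such low shares cannot tell list length from other causes. A search chosen after the results were seen took regions above the median strength of the 5 other lists. Of these 159 were missing from wild-type HSC, the shortest list, and 15 from knockout HSC. An effect of Kmt2c loss on weak or stronger regions stays open and was not tested apart from list length.

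The larger number of regions found only in wild-type HPC was weighed against list length, since 4 wild-type and 2 knockout samples name these lists, though how their reads were combined was not known. Of the wild-type-only regions 3.78% (3.51 to 4.08) of 17025 lay above the median strength of the wild-type HPC list, a low share that list length predicts. But of 3677 regions only in the shorter knockout HPC list, 0.734% lay above the median of that list. The share is thus low in the shorter list too and cannot tell list length from other causes. A loss of weak regions without Kmt2c would look the same in these lists and was not tested apart from list length.

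The 27 regions in both knockout lists and in no wild-type list, near Ncs1, Stat3, Etv6, Rxra and others, could have come from a segment of another strain carried along with the Kmt2c allele. Of these 0 lay within 20 Mb of Kmt2c, which allows up to 12.5%, against 1.39% of all knockout HSC regions, and this argues against such a segment as the source of most of them. Among the 873 regions of the reverse kind 13, or 1.49%, lay that close. Chance at weak regions and an effect of Kmt2c both stay open and were not tested.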

How the results depend on the processing

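The nearest gene end and the settings applied to single genes were chosen after the data were seen. An overlap of 50% of the shorter region, absence only with nothing within 1 kb and autosomes alone moved none of the 10 counts of regions in a single list by 1.5 times and none of the 8 shares beyond its interval. Over all settings 43 of 70 counts and 28 of 48 shares stayed that close. Where values moved, the cause was not tested, apart from equal numbers, which make the counts of a pair nearly equal by construction and draw the classes behind the shares anew. Read depth was not known, so what depth limits could not be given. No paired analysis was possible because the files used here hold a single list per group, and for the same reason no replicate was left out. The motif alternatives were not run.

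At equal number, regions only in knockout and only in wild-type HSC were 6148 and 6042, in HPC 6717 and 7148, those only after 5-fluorouracil and only in vehicle 6373 and 6712, and those only in wild-type HSC and only in wild-type HPC 9508 and 9729. With 200 bp summit windows these pairs were 19744 and 8241, 6708 and 28428, and 12641 and 28706, regions only in wild-type HSC against HPC were 7441, and those only in knockout HSC against HPC 18355. Above the median strength of their list and absent from the full other list were 675 knockout and 64 wild-type HSC regions, 27 knockout and 644 wild-type HPC regions, 20 regions after 5-fluorouracil and 99 in vehicle, 420 of wild-type HSC and 6131 of wild-type HPC, and 1424 of knockout HSC and 2651 of knockout HPC. With the weakest 25% removed 2072 regions were only in knockout HPC.

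Among wild-type-only and knockout-only HSC regions in exactly 1 HPC list, the share in the wild-type one was 91.5% and 87.7% with the weakest 25% removed, 62.5% and 51.3% at equal number and 80.4% and 80.0% with summit windows. Among regions in exactly 1 of the 8-week HSC lists, the knockout share of those only after 5-fluorouracil, only in vehicle and in both was 43.9%, 57.7% and 55.0% at equal number and 65.9%, 76.1% and 69.9% with summit windows, and that of regions in both 76.8% with the weakest 25% removed. For stem cell regions, progenitor regions and regions in both it was 52.2%, 54.0% and 59.4% at equal number and 70.1%, 74.0% and 70.6% with summit windows, and that of regions in both 76.1% with the weakest 25% removed.

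Of 50 percentiles of the lists that stood apart, 36 stayed outside the bounds on the same side. The interleukin-1, TNF and NF-kB list in knockout against wild-type HPC lay at 78.9 with the weakest 25% removed and, on the other side of the middle, at 44.7 at equal number. In wild-type HSC against HPC it was at 95.9 with genes within 20 kb, 97.4 with all annotated genes, 81.3 at equal number and 87.0 with the weakest 25% removed. Neutrophil genes with 5-fluorouracil lay at 78.6 with all annotated genes and, on the other side of the middle, at 40.7 with the weakest 25% removed. Macrophage genes in knockout against wild-type HSC were at 97.0 at equal number, erythroid and megakaryocyte genes with 5-fluorouracil at 97.2 and self-renewal genes in knockout HSC against HPC at 96.7 with the nearest gene end. With all annotated genes mature B cell genes were at 3.45 in wild-type and 12.9 in knockout HSC against HPC, and T and NK cell genes at 4.76 in the latter.

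Of 640 net numbers of regions per named gene, 524 stayed within 1.5 times, 111 moved and 5 reversed. Equal numbers shorten only the longer list, so genes named for the shorter one could not lose their excess there. At equal number Gse1 had a net of −1 in vehicle over 5-fluorouracil and Pde4d of −2 in wild-type HPC over HSC. With the weakest 25% removed Sgms1 had −1 in 5-fluorouracil over vehicle. With the nearest gene end 40 of 80 stayed within 1.5 times, 38 moved and 2 reversed. These were Lsamp with −1 in wild-type HSC over HPC and Nav2 with −3 in knockout HSC over HPC.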

Other observations

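The search for strong regions missing from a single list and the weighting by strength were chosen after the results were seen. Of regions in the top 10% by −log10 p of 5 lists, 6 had nothing within 1 kb in the remaining list. Those missing from knockout HSC lay within Slc8a1, at an end of Tnks1bp1, which encodes a tankyrase-binding protein, at 85047486 to 85048949 on chromosome 2, and within Stim1. Those missing from knockout HPC lay at an end of Dync1i2 and within Arhgap35. The region missing after 5-fluorouracil lay outside Lonrf1, at 36183929 to 36184451 on chromosome 8, with a fold enrichment of 29.6 in wild-type HSC and 20.3 in vehicle HSC. The Slc8a1 region had a fold enrichment of 35.8 in knockout HPC, and that at Dync1i2 40.0 in knockout HSC. Among regions above the median strength of 5 lists, 159 were missing from wild-type HSC, 15 from knockout HSC, 4 from wild-type HPC, 53 from knockout HPC, 2 from vehicle HSC and 6 after 5-fluorouracil.

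Regions found in a single list were looked up in the 4 lists outside their comparison. These included the long vehicle and 5-fluorouracil lists for the genotype comparison and only shorter lists for the treatment, so the shares are not comparable between them. Regions in none of the other lists made up 2.32% (2.07 to 2.60) of knockout-only and 1.35% (1.04 to 1.76) of wild-type-only HSC regions. They made up 64.9% (63.4 to 66.4) of regions only after 5-fluorouracil and 63.3% (62.5 to 64.1) of vehicle-only ones. Wild-type HPC held 1201 of 4002 regions only after 5-fluorouracil and 3616 of 12993 vehicle-only ones.

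Regions open in both the 5-fluorouracil and vehicle lists, weighted to the strength of those found only after 5-fluorouracil, were held by knockout HSC at 16.9% and by wild-type HSC at 7.25%, above the 6.77% and 2.37% measured. Weighted to vehicle-only regions they were held at 12.2% and 5.21%, against 11.8% and 4.63%. Regions in both vehicle HSC and wild-type HPC, weighted to the strength of stem cell regions, were held at 34.1% and 21.7%, against 22.0% and 12.0%. Weighted to that of progenitor regions they were held at 51.4% and 39.1%, against 5.42% and 1.86%. Regions in both were picked for being in both lists, and progenitor regions for being absent from an HSC list. Weighting by strength does not remove this selection, so these gaps do not show a depletion beyond strength. The knockout share of regions in exactly 1 of the 8-week HSC lists was 80.0% and 79.2% after weighting to the regions only after 5-fluorouracil and only in vehicle, and 75.8% and 73.4% after weighting to stem cell and progenitor regions.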
